A study of Papio with 24 samples.

How the data were processed

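Adipose-derived stem cells of 8 baboon fetuses were compared by the study on 24 single-channel Illumina bead arrays carrying human probes. Per the labels' protocols, fat was taken from the omentum, the subcutaneous abdomen and the subcutaneous femoral region of fetuses at 165 days of gestation, with term at 184 days. Mothers had eaten freely (4 control fetuses, labelled control_9017, control_9087, control_8011 and control_8009) or had received a diet restricted by 30% through pregnancy (4 restricted fetuses, labelled restricted_9085, restricted_2820, restricted_9075 and restricted_9073). Each diet group held 1 male fetus (control_9017 and restricted_9085) and 3 female fetuses. Cells were released with collagenase, grown in medium with 10% fetal bovine serum, frozen, thawed and grown to confluence in wells whose RNA was pooled, so each array read 1 fetus and 1 depot. The arrays therefore measured cultured cells, not fat tissue. Biotin-labelled cRNA was made from total RNA, per the labels' protocols.

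The authors deposited a table with an average intensity per probe and array, per the file headers. These values had been background-subtracted and were not normalised between arrays, as read from the values: 32.0% to 37.7% of an array's values lay below 0, and array means ran from 148 to 211. Per the file headers, the deposited table also gave a detection p-value per probe and array. The authors also deposited intensity values in a series matrix. From the values, these were quantile-normalised intensities on a linear scale, because each column had the rank order of its own scanner column (rank correlation 1, against at most 0.886 with the best other column) and column medians ran only from 2.90 to 2.91. Software and settings of the scanner and of that normalisation are not given in the sources used here. Array columns were matched to samples by depot letter and fetus number, and this rank order bore the match out for all 24 arrays. The number of arrays limits the precision of every comparison, and dim probes carry little signal over background. Between 13102 and 14994 of the 48803 probes (26.8% to 30.7%) were detected on an array at a detection p under 0.05.

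Gene names came from the platform annotation held by GEO, which can be old. Of the 48803 probes, 28098 had 1 gene symbol, 13 had several and 20692 had none, and no gene was named from a probe of the last 2 kinds. Mismatches between human probes and baboon transcripts were not assessed, so no probe's level was set against another probe's.

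Background was modelled and values were quantile-normalised and put on the log2 scale with neqc (offset 16) in limma 3.58.1 under R 4.3.3, with statmod 1.5.0. A probe was tested if its detection p was under 0.05 on at least 4 of the 24 arrays, which kept 16933 probes, of which 12863 had 1 symbol and covered 10228 genes. Limma's lmFit and eBayes gave two-sided tests with Benjamini-Hochberg adjustment over the tested probes, and a call needed an adjusted p under 0.05. Differences are log2 differences of means with standard errors. Diet was tested as restricted minus control within the 8 arrays of each depot and on means over the 3 depots of each fetus. Depots were compared over the 16 arrays of each pair, with diet in the model. Depot by diet interactions were tested on the same arrays. A probe not detected on any array of a group has only a bound there, printed as "at least N-fold". For ZNF331 and TBX1 another probe of the gene was detected on some arrays of such groups, so their bounds hold for the probe and not for the gene. It sets the brighter group's mean against the mean, over the arrays of the dimmer group, of the higher of the array's lowest detected signal and the probe's own value. Tables were handled in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and plots were drawn with matplotlib 3.10.9.

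Lists of genes were tested with camera at a preset correlation of 0.01, with 1 probe per gene (the one with the highest mean over all arrays) and adjustment over the 29 lists of a comparison. They covered visceral fat identity, subcutaneous fat identity, anterior HOX, posterior HOX and hindlimb identity genes. They also covered adipocyte differentiation, preadipocyte and anti-adipogenic genes, thermogenic genes, the insulin-like growth factor axis and imprinted genes. Further lists held extracellular matrix, contractile, bone and cartilage, cell cycle, cholesterol synthesis and oxidative phosphorylation genes. Others held hypoxia and glycolysis genes, interferon response genes, cytokines and NF-kB targets, glucocorticoid targets, unfolded protein and amino acid stress genes, and growth-factor-induced immediate early genes. The rest held markers of mesothelial, endothelial, macrophage and blood, pericyte, skeletal muscle, epithelial and keratinocyte, and Schwann and neural cells. Of 542 listed genes, 507 were on the array and 362 were tested. Counts of members adjusted over the list alone stand beside counts over all probes, and every list call was repeated with a correlation estimated from the data.

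Named genes followed a rule. Per comparison these were the 10 passing genes with the largest difference in each direction, the 5 with the smallest p in a direction where fewer than 3 passed, up to 4 members of each list with the smallest p, and PPARG, CEBPA, FABP4, LPL, DLK1, IGF1, IGF2, IGFBP2, IGFBP3 and IGFBP5 where detected. A part of these is named in the text. Comparisons, lists, this rule and most alternatives were fixed before the data were examined.

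The 3 depots of a fetus come from 1 animal, so fetus numbers pair the samples. Deviations from group means correlated at 0.28 to 0.67 between depots of the same fetus (median 0.457, 24 pairs) and at -0.47 to 0.21 between different fetuses of the same diet. The depot comparisons had no block, and the fit with the fetus as a block is an alternative. Other alternatives were the series matrix values (log2, with values at or below 0 set to the lowest positive value, which spreads dim probes widely), no background correction, median scaling, no filter and a strict filter (detection p under 0.01 on every array compared), an intensity trend with robust moderation, array weights, sex as a covariate, female fetuses only, 1 probe per gene, all arrays in 1 fit with or without the fetus as a random block, all probes of listed genes, and each fetus left out in turn.

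The steps were tested on simulated arrays of the 16933 probes, of which 200 were changed, 50 by each size. For the diet comparison in omental cells, 23 of 50 probes changed by 0.5, 44 of 50 changed by 1 and 46 of 50 changed by 2 (log2) were called, and for the diet comparison averaged over depots these counts were 26, 41 and 49. For omental versus femoral cells they were 35, 45 and 50, and for the diet by depot interaction of omental and femoral cells they were 8, 41 and 46. False calls were 10 of 173, 12 of 176, 8 of 188 and 9 of 153 in these 4 simulations. The contractile list, shifted by 0.5, was called in 10 of 10 simulations of each comparison, and at most 1 of 280 unshifted lists was called at the preset correlation. Simulated genes varied independently of each other, unlike genes in real cultures. The 200 changed probes also ease the adjusted threshold, so fewer changes of these sizes would be called where few probes change.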

Results

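Transcript levels were read in cultured adipose-derived stem cells of 8 baboon fetuses, with 1 array for each of 3 depots per fetus. These cells are the progenitors that can form fat cells, and the depots were omental fat inside the abdomen, subcutaneous abdominal fat and subcutaneous femoral fat of the thigh. Each of the 6 groups of depot and maternal diet held 4 arrays, from 4 control or 4 restricted fetuses. Arrays detected 13102 to 14994 probes, with mean signals of 148 to 211, and 16933 probes were tested. The number of arrays limits the precision of every value. XIST and RPS4Y1 matched the labelled sex of all 24 arrays, while 10 probes of 6 other genes of the Y chromosome were detected on no array and decide nothing. RPS4Y1, on the Y chromosome, averaged 12.3 ± 0.03 in the 2 males and 4.98 ± 0.08 (SD) in the 6 females on the log2 scale, and XIST averaged 5.20 ± 0.21 in males and 6.56 ± 0.09 in females. The exact two-sided permutation p was 0.0357 for each, the smallest that 28 splits allow.

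**Figure D1:**
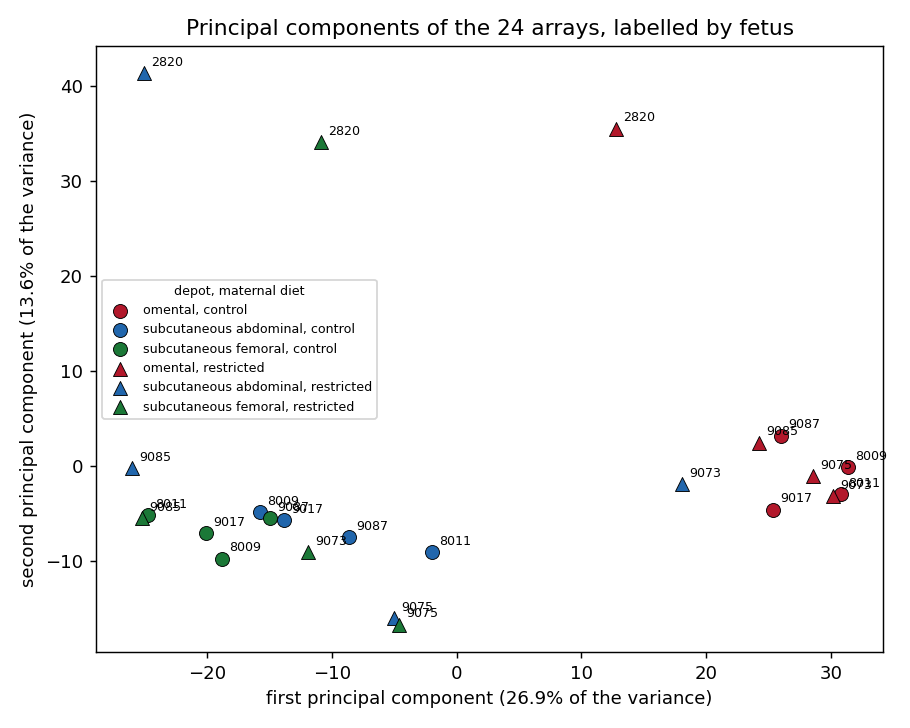
First and second principal components of the 24 arrays, holding 26.9% and 13.6% of the variance, with colours for depots, circles for control and triangles for restricted fetuses, and the numbers of the fetuses beside the points. Omental arrays had the higher values on the first component, the abdominal array of fetus restricted_9073 lay among them at 18.1, and the 3 arrays of fetus restricted_2820 lay apart on the second at 34.1 to 41.4.

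The series asks whether a restricted maternal diet changed fetal fat progenitors in a depot-dependent way, and omental cells were compared first. Interferon response genes, which cells switch on when they sense a virus, stood higher as a list in restricted fetuses. So did genes of hypoxia and glycolysis, immediate early genes that growth factors induce, cytokines with NF-kB targets, epithelial markers and cell cycle genes. No single gene passed, and none of these list calls held with an estimated correlation (adjusted p = 0.56 to 0.945 with an estimated correlation). Limma called 0 of 16933 probes, and 804 had an unadjusted p under 0.05, against 847 by chance.

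Among the omental genes with the smallest p, ZNF331, a zinc finger gene, differed by -0.85 ± 0.12 (log2, SE; limma adjusted p 0.357). This probe was not detected on the 4 restricted arrays and was at least 1.33-fold higher in controls, and it passed with all 24 arrays in 1 fit without a block (0.0212). MEG3, an imprinted noncoding RNA, differed by -0.74 ± 0.12 (adjusted p 0.357), and all 4 restricted arrays lay below all 4 control arrays. The planar polarity gene PRICKLE1 differed by 0.74 ± 0.12, the pregnancy-specific glycoprotein PSG3 by 1.58 ± 0.31 and the decoy receptor TNFRSF11B by 1.54 ± 0.32 (adjusted p 0.357 to 0.614). ERCC1, a DNA repair gene, differed by -1.29 ± 0.20 (adjusted p 0.357) and passed without fetus restricted_9073 (0.0388), but only 3 of its 4 probes pointed the same way. The growth factor IGF2 differed by -1.30, its binding proteins IGFBP3 by -0.51 and IGFBP5 by 0.62, the fat regulator PPARG by -0.48 and the ETS factor ETV4 by 0.85, none passing. Leaving out fetus restricted_9085 or control_9087 gave 1 call each and leaving out restricted_9073 gave 2.

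The omental interferon list had a mean difference of 0.94 over 12 genes, all higher (adjusted p 0.00172; adjusted p = 0.895 with an estimated correlation), and without fetus restricted_2820 its mean difference was 0.203 (adjusted p 0.132). Its members IFI27 (2.16, at least 3.48-fold) and IFI6 (1.39) did not pass. The hypoxia and glycolysis list differed by 0.29, with 15 of 18 genes higher (adjusted p 0.00208; adjusted p = 0.895 with an estimated correlation), and by 0.0372 (0.83) without restricted_2820. Its members NDRG1 (0.42) and GAPDH (0.39) did not pass. The immediate early list differed by 0.21 with 13 of 14 genes higher (0.00527; adjusted p = 0.56 with an estimated correlation; mean 0.162 and adjusted p 0.176 without restricted_2820). The cytokine list differed by 0.38 with 12 of 14 higher, among them IL6 (1.24) and SOD2 (0.64). Its adjusted p was 0.00897, and adjusted p = 0.56 with an estimated correlation, 0.176 without restricted_2820, where the mean was 0.187, and 0.156 without control_8009. It was also lost without a filter on dim probes (0.317) and with probes detected on every array (0.0839), as was the immediate early call with the latter (0.0839). Epithelial markers differed by 0.48, with EPCAM at 0.73 (0.0334; adjusted p = 0.56 with an estimated correlation). Leaving out control_9017, restricted_9085, control_9087, control_8011 or restricted_9073 ended this call (0.128, 0.0673, 0.0961, 0.0506 and 0.0739). Cell cycle genes differed by 0.21, with TOP2A at 0.43 (0.0458; adjusted p = 0.945 with an estimated correlation). Leaving out control_9017, restricted_2820, restricted_9075 or restricted_9073 ended the call (0.234, 0.687, 0.0789 and 0.596), and without control_8009 the list mean was -0.0051 (0.988). The epithelial and cell cycle calls were also lost without a filter (0.362 and 0.149) and with the series matrix values (0.0787 for each). Without restricted_2820, 1 list was called in place of 6. No member of these 6 lists passed over all probes or adjusted over the list alone.

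In subcutaneous abdominal cells, visceral fat identity genes, among them transcription factors that mark progenitors of deep fat, stood higher as a list in restricted fetuses. Hypoxia and glycolysis genes and interferon response genes did too. None of the 3 list calls held (adjusted p = 0.192, 0.962 and 0.962 with an estimated correlation). Single genes did not pass: limma called 0 of 16933 probes, and 824 had an unadjusted p under 0.05, against 847 by chance. Without restricted_9085, 1 probe was called.

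The visceral list differed by 0.51 with 9 of 10 genes higher (adjusted p 0.000473; adjusted p = 0.192 with an estimated correlation). Its mean was 0.321 without the abdominal array of fetus restricted_9073. Once fetus restricted_2820 was left out as well, it was 0.13 and no longer called (0.407). Both alternatives were chosen after seeing the data. Its members FOXF1 (0.76), HAND2 (0.27) and GPC4 (0.61) did not pass. The hypoxia list differed by 0.23, with NDRG1 at 0.38 (0.00993; adjusted p = 0.962 with an estimated correlation), and its call ended without restricted_9085 (0.0511), control_9087 (0.116) or restricted_2820 (0.689, at a mean of 0.0479). The interferon list differed by 0.42, with IFI6 at 0.87 (0.0161; adjusted p = 0.962 with an estimated correlation), and its call ended without control_9017 (0.0873), control_9087 (0.0529), restricted_2820 (0.913, at a mean of 0.0561) or control_8011 (0.0572). No member of the 3 lists passed adjusted over the list alone. The number of called lists became 1 without control_9087, 5 without restricted_9075 or restricted_9073 or the abdominal array of restricted_9073 alone, and 7 without control_8009. The smallest p values were those of ARPP21 (-1.44 ± 0.19, adjusted p 0.538), PGAP4 (0.82 ± 0.12, 0.538), ABLIM1 (-0.98 ± 0.16, 0.557), TNFRSF11B (1.84 ± 0.32, 0.557), RCAN1 (1.20 ± 0.21, 0.557) and ZNF331 (-0.76 ± 0.13, 0.557, its probe at least 1.32-fold higher in controls), each with no overlap between the diets' arrays. IGFBP3 differed by -0.78 ± 0.33 (0.955).

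In subcutaneous femoral cells, oxidative phosphorylation genes, which build the respiratory chain of mitochondria, stood slightly higher as a list in restricted fetuses, as did the hypoxia and interferon lists. Imprinted genes, expressed from a single parental copy and many of them regulators of fetal growth, stood lower as a list. None of the 4 list calls held (adjusted p = 0.789 to 0.816 with an estimated correlation). Limma called 0 of 16933 probes, and 1050 had an unadjusted p under 0.05, against 847 by chance. Without restricted_9085, 5 probes were called, and without restricted_9073, 1.

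The femoral imprinted list differed by -0.25 (adjusted p 0.0323; adjusted p = 0.789 with an estimated correlation). Of its 15 genes, 0 passed over all probes, while 5 passed as lower and 1 as higher adjusted over the list alone. MEG3 differed by -0.76 ± 0.12 (adjusted p over all probes 0.476), PEG3 by -0.55 ± 0.13, CDKN1C by -0.61 ± 0.19, IGF2 by -1.35 ± 0.44 and NNAT by 1.52 ± 0.34 (0.476 to 0.764), and for each the 4 restricted arrays lay on 1 side of the 4 control arrays. The call ended without control_9017 (0.138), restricted_9085 (0.0561), control_9087 (0.0551) or restricted_2820 (0.171). It also ended with probes detected on every array (-0.0784, 0.434), with all probes of each gene (-0.142, 0.0995), without a filter (0.15), with sex in the model (0.0525), with female fetuses alone (0.176), with all 24 arrays in 1 fit (0.202 with a random block and 0.157 without), without background correction (0.0727) and with the series matrix values (0.0739). The oxidative phosphorylation list differed by 0.13 with 20 of 24 genes higher, NDUFV2 by 0.49 and UQCRH by 0.35 (list adjusted p 0.00684; adjusted p = 0.789 with an estimated correlation; 0.0841 without restricted_9075). The hypoxia list differed by 0.23 with 17 of 18 genes higher, LDHA by 0.26 (0.0123; adjusted p = 0.789 with an estimated correlation; mean 0.0495 and adjusted p 0.62 without restricted_2820). The interferon list differed by 0.58, IFI44 by 1.27 (0.0433; adjusted p = 0.816 with an estimated correlation), and its call ended without control_9017 (0.138), control_9087 (0.114), restricted_2820 (0.918, at a mean of 0.0179), control_8011 (0.0718) or control_8009 (0.0595). Leaving out control_9017, control_9087 or restricted_2820 left 2 called lists in place of 4. The fat regulators CEBPA (-1.25 ± 0.39, adjusted p 0.751) and PPARG (-0.89 ± 0.34, 0.78) did not pass, nor did KITLG (-1.11 ± 0.18, 0.476), which passed without restricted_9085 (0.0331). ZNF331 differed by -0.92 ± 0.14 (0.476, the probe at least 1.51-fold higher in controls; 0.0188 with all 24 arrays and the fetus as a random block and 0.0126 without it), IGSF1 by 0.76 ± 0.13 and SPINT2 by 0.78 ± 0.15 (both 0.524).

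Averaged over the 3 depots of each fetus, ZNF331 was the only gene called, and it was lower in restricted fetuses. MEG3 and CDKN1C, an imprinted brake on the cell cycle, were lower without passing. IGF2 was too. The inflammatory genes IL6 and CXCL8 differed by 1.18 and 1.95 without passing, and by 0.73 and 0.70 without fetus restricted_2820. Limma called 1 of 16933 probes, and 1051 had an unadjusted p under 0.05, against 847 by chance.

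ZNF331 fell by 0.84 ± 0.07, from 5.25 ± 0.10 in controls to 4.41 ± 0.09 (SD, n = 4 and 4; limma adjusted p 0.0233). This probe was detected on all 12 control arrays and no restricted array, so its signal was at least 1.38-fold higher in controls. All 4 restricted fetuses lay below every control. A second probe, detected on 3 control and 4 restricted arrays, differed by 0.01 ± 0.05. The call ended without restricted_9085 (0.0545), control_8011 (0.0984), restricted_9075 (0.136), control_8009 (0.183) or the abdominal array of restricted_9073 (0.0506). Sex in the model (0.0562), female fetuses alone (0.0979) and median scaling (0.051) ended it. So did no background correction (-13.1, 0.696) and the series matrix values (-14.5, 0.721), whose floor enlarged the difference. Without control_9017, restricted_2820 or restricted_9073, 3 probes were called. PGAP4 (0.69 ± 0.09), ETV4 (0.66 ± 0.09 and 0.80 ± 0.12 on 2 probes), the integrin ITGA8 (1.36 ± 0.20), MEG3 (-0.80 ± 0.12) and the stress factor ATF4 (-0.54 ± 0.08) had adjusted p values of 0.309. NDNF (1.19 ± 0.19, 0.309) passed without restricted_2820 (0.00338), and SOX8 differed by -1.02 ± 0.17 (0.381). CDKN1C differed by -0.87 ± 0.21 (0.694), IGFBP3 by -0.46 ± 0.11 (0.694), IGF2 by -1.11 ± 0.35 (0.783) and CEBPA by -0.67 ± 0.26 (0.8). With all 24 arrays in 1 fit and the fetus as a random block, 22 probes were called, among them MEG3 (0.0353) and PGAP4 (0.00241).

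Lists called on the averages were hypoxia and glycolysis (0.25, NDRG1 0.34; adjusted p 0.00191), interferon response (0.65, IFI27 1.56; 0.00857), cytokines (0.44, IL6 1.18, CXCL8 1.95; 0.0218) and cell cycle (0.13, AURKB 0.30; 0.0458). None held, each with adjusted p = 0.888 with an estimated correlation, and no member passed adjusted over the list alone. Without fetus restricted_2820, 0 lists were called, with means of 0.0449, 0.0924, 0.0943 and 0.176 and adjusted p values of 0.491, 0.234, 0.852 and 0.101 in that order. The cytokine call also ended without control_8009 (0.0775), and the cell cycle call without control_9017 (0.863), restricted_9075 (0.434) or restricted_9073 (0.0868).

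**Figure D2:**
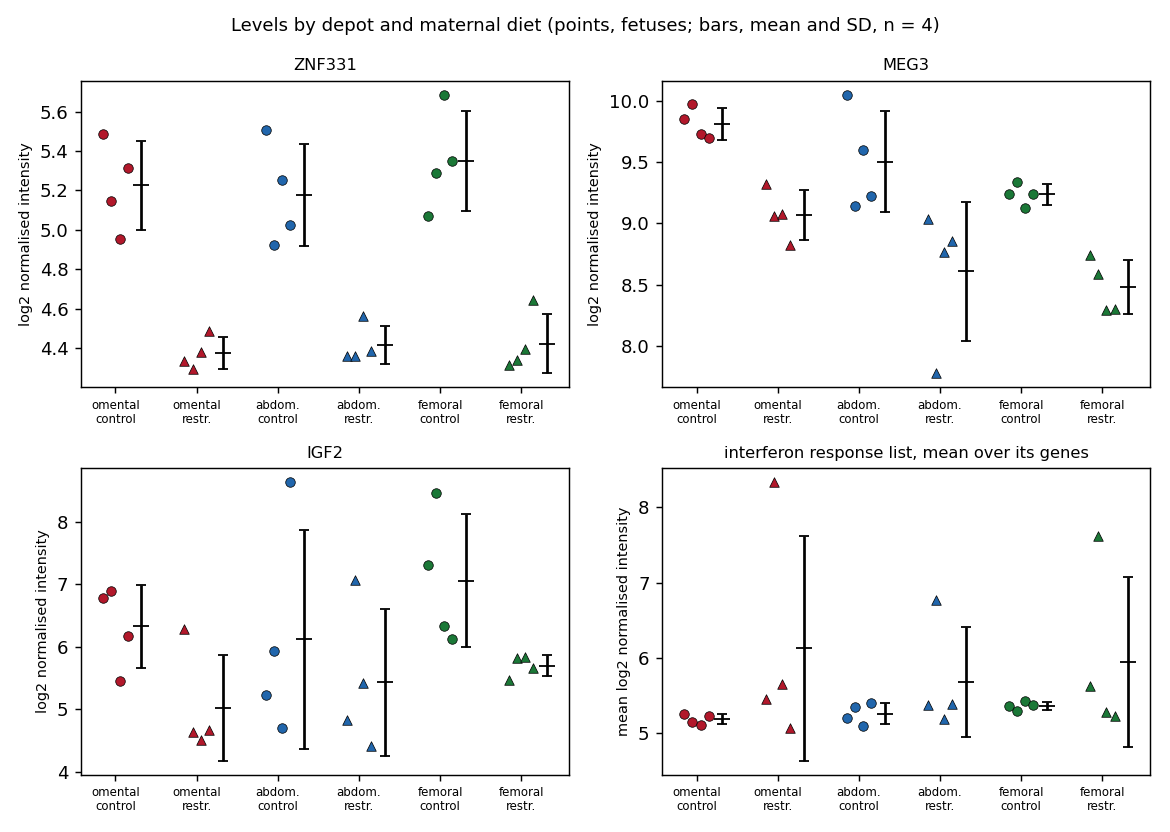
Log2 normalised intensity of ZNF331, MEG3 and IGF2 and the mean of the interferon response list, per fetus, for 6 groups of depot and maternal diet, with bars for mean and SD (n = 4). ZNF331 and MEG3 did not overlap between the diets in any depot, while the higher interferon means of restricted fetuses came from fetus restricted_2820.

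Omental and subcutaneous abdominal cells differed in lists of fat identity and in single genes. The visceral identity list was higher and the subcutaneous identity list lower in omental cells, and both held with an estimated correlation. NKX3-2, WT1, ISL1 and HAND2, which mark the lining and mesoderm of the gut region, were higher in omental cells. HOXC8, TBX15, EN1, PRRX1 and TWIST2, which pattern the trunk wall and limbs, were higher in abdominal cells. The smooth muscle gene CNN1 and the basement membrane collagen genes COL4A1 and COL4A2 were higher in omental cells, and the surface markers CD248 and ANPEP were lower. PPARG, the master regulator of fat cell formation, was higher in omental cells, whereas CEBPA, its partner, was lower.

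Limma called 680 probes, 368 higher and 312 lower in omental cells, which were 287 genes higher and 242 lower. With the fetus as a block, 1439 were called. The count was 409 without control_9017, 282 without restricted_9085, 367 without control_9087, 396 without control_8011, 372 without restricted_9075, 276 without control_8009 and 1082 without the abdominal array of restricted_9073. NKX3-2 was higher by 5.10 ± 0.57, at 10.2 ± 0.37 against 5.12 ± 1.80 (SD, n = 8 and 8; adjusted p 0.000172), in 8 of 8 fetuses. HOXC8 was lower by -3.90 ± 0.23 (3.7e-07) and TBX15 by -2.44 ± 0.15 (3.7e-07, at least 4.29-fold), both in 8 of 8 fetuses, though TBX15 missed the threshold with the series matrix values (0.0563). Other genes higher in 8 of 8 fetuses were the muscle protein gene PDLIM3 (3.13), the retinoic acid enzymes ALDH1A1 (2.75) and ALDH1A2 (2.19), SNAP25 (2.45) and APOA1 (2.33), with adjusted p values of 0.000172 to 0.0221. The calcium pump regulator SLN (4.42 ± 0.82, 0.00711) was higher in 7 of 8. Genes lower in 8 of 8 were LAMA2 (-3.45), STMN2 (-3.05) and MME (-2.68), and IRX2 (-3.65, at least 9.68-fold) and IRX5 (-3.19) were lower in 7 of 8 (7.7e-05 to 0.00276). With the series matrix values SNAP25 (0.126) and LAMA2 (0.183) did not pass.

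The subcutaneous identity list was lower by a mean of -0.70 in omental cells (adjusted p 1.68e-06). Of its 10 genes, 6 passed over all probes as lower, and 7 lower and 1 higher adjusted over the list alone, among them PRRX1 (-0.96), EN1 (-0.60, at least 1.36-fold) and TWIST2 (-1.30, lost without restricted_9075 at 0.056). The visceral identity list was higher by 1.22 (8.97e-06), with 5 of 10 genes passing and 6 adjusted over the list alone, among them ISL1 (2.41), WT1 (1.69) and HAND2 (0.60, higher in 7 of 8 fetuses). Pericyte markers were lower by -0.63 (0.00204), with 2 of 8 passing and 3 adjusted over the list alone. These were CD248 (-1.84) and ANPEP (-1.88), lower in 8 of 8 fetuses, over all probes. These 3 lists held with an estimated correlation (0.0399, 0.0363 and 0.0399). The contractile list was higher by 0.57 with 13 of 13 genes positive (3.69e-06; adjusted p = 0.171 with an estimated correlation), 4 passing and 8 adjusted over the list alone. CNN1 was higher by 1.26 and TPM1 by 0.53, the latter lost without control_9017 (0.0666), restricted_9085 (0.0712), control_9087 (0.0711), restricted_2820 (0.0634), restricted_9075 (0.0634) or control_8009 (0.104).

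Cell cycle genes were lower by -0.46 with 24 of 24 negative (5.5e-06; adjusted p = 0.517 with an estimated correlation), 2 passing and 5 adjusted over the list alone. The list was lower in only 5 of 8 fetuses, and the mean over fetuses was -0.298 without control_8009. The replication helicase genes MCM5 (-1.13, 0.0238) and MCM7 (-0.84, 0.0425; 0.073 with the block) were lower in 8 and 7 of 8 fetuses. MCM5 did not pass without control_9017 (0.0607), restricted_9085 (0.0629), control_9087 (0.0683), restricted_9075 (0.0665) or control_8009 (0.107), and MCM7 did not without control_9017 (0.0732), restricted_9085 (0.0941), control_9087 (0.098), control_8011 (0.0705), restricted_9075 (0.102) or control_8009 (0.167). The hypoxia list was lower by -0.40 with 17 of 18 negative (0.000102; adjusted p = 0.495 with an estimated correlation), 1 passing and 2 adjusted over the list alone. That 1 was LDHA (-0.45, 0.0431), which passed without control_9017 but with no other fetus left out (0.0522 to 0.141). Cytokines were lower by -0.56 (0.0268; adjusted p = 0.71 with an estimated correlation), with 0 passing over all probes or adjusted over the list alone, and the call ended without control_9017 (0.0757) or restricted_2820 (0.0675). SOD2 (-1.37, 0.165) passed with the fetus as a fixed block (0.0311) or a random one (0.0242).

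PPARG was higher in omental than abdominal cells by 1.19 ± 0.26 (0.0171, 8 of 8 fetuses) and did not pass without control_9087 (0.0663), control_8011 (0.0533) or control_8009 (0.0717). CEBPA was lower by -1.54 ± 0.31 (0.0126, 8 of 8) and did not pass without control_8009 (0.0635) or with the series matrix values (0.163). ALDH1A1 did not pass without restricted_9085 (0.0629). APOA1 did not without restricted_9085 (0.0886), control_9087 (0.0881), control_8011 (0.065), restricted_9075 (0.0847) or control_8009 (0.0635). IGF1 was higher by 0.74 ± 0.18 (0.0299, 7 of 8) and kept its call only without restricted_2820 or control_8011 (otherwise 0.0582 to 0.112). HOXB5 (1.91) and HOXB6 (1.20) were higher and HOXC6 (-1.90) lower in omental cells of 8 of 8 fetuses (1.83e-05 to 0.000887), with 1 of 3 HOXC6 probes pointing the other way. The collagen genes COL4A1 (0.75) and COL4A2 (1.10) were higher and the protease inhibitor TIMP3 (-1.12) lower in 8 of 8 (0.00271 to 0.00682).

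Omental and femoral cells differed in more probes. HOXA2, HOXB5, HOXB6 and HOXB8 were higher in omental cells, and HOXC6, HOXC8, HOXC9 and HOXC10 were lower. PITX1, which specifies the hindlimb, and the limb and skin factors TBX15, PRRX1 and LHX2 were higher in femoral cells. TBX1 and EBF2, linked to heat-producing fat, and CD34, a surface marker of progenitors, were also higher there. Omental cells had more PPARG, the fatty acid receptor CD36, WT1, CALB2 and KRT19. The last 3 mark mesothelium, but the mesothelial list had 4 genes higher and 2 lower and was not called (0.184). Its mean was nonetheless higher in omental than femoral cells in 8 of 8 fetuses (0.62), and than abdominal cells in 7 of 8 (0.39).

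Limma called 1780 probes, 851 higher and 929 lower in omental cells, which were 658 genes higher and 728 lower. NKX3-2 was higher by 5.27 ± 0.32, at 10.2 ± 0.37 against 4.95 ± 0.91 (SD, n = 8 and 8; adjusted p 5.32e-08), in 8 of 8 fetuses. Also higher in 8 of 8 were SLN (5.21), PDLIM3 (3.69), HOXB8 (3.21), PLA2G7 (2.67) and, on 1 of its 2 probes, CALB2, with adjusted p values of 3.89e-07 to 0.000152. TBX15 was lower by -3.58 ± 0.15 (1.49e-09, at least 9.46-fold) and CD34 by -3.81 ± 0.30 (6.63e-07), both in 8 of 8 fetuses. HOXC8 (-3.76), LAMA2 (-3.75), IRX5 (-3.71), IRX2 (-3.14, at least 6.81-fold) and PITX1 (-3.14) were lower in 8 of 8 as well (5.39e-09 to 0.0008). With the series matrix values LAMA2 (0.0941) and PITX1 (0.0961) missed the threshold.

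The pericyte list was lower by -1.07 in omental cells (5.82e-06), with 5 of 8 genes passing and 5 adjusted over the list alone, ANPEP (-2.50), CD248 (-2.12) and PDGFRB (-0.72) in 8 of 8 fetuses. The subcutaneous identity list was lower by -0.92 (2.76e-06), with 7 of 10 passing and 7 adjusted over the list alone, PRRX1 by -1.52. The visceral identity list was higher by 1.19 (0.000642), with 5 genes higher and 1 lower over all probes and 6 and 2 adjusted over the list alone. WT1 (1.89) and HAND2 (1.31) were higher, and LHX2 (-1.65, at least 2.33-fold) was lower, in 8 of 8. The thermogenic list was lower by -0.84 (0.00744), with 3 of 5 genes lower, and 3 lower and 1 higher adjusted over the list alone. TBX1 was lower by -2.77 (at least 4.84-fold, with 2 of 3 probes in this direction) and EBF2 by -1.05, and the list was not called with the series matrix values (0.508), without background correction (0.506) or without a filter on dim probes (-0.302, 0.116). The preadipocyte list was lower by -0.56 (0.00903), with 5 of 16 passing and 7 adjusted over the list alone, TCF7L2 by -0.81 and JAG1 by -0.68 (7 of 8 fetuses), and was not called with probes detected on every array (-0.369, 0.0991). These 5 lists held with an estimated correlation (0.00596, 0.0131, 0.0144, 0.0455 and 0.0455).

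The contractile list was higher by 0.54 (1.31e-05; adjusted p = 0.0992 with an estimated correlation), with 7 of 13 passing and 8 adjusted over the list alone, CNN1 by 1.54 and ACTG2 by 0.83. The hypoxia list was lower by -0.33 (0.00237; adjusted p = 0.471 with an estimated correlation), with 4 of 18 passing and 4 adjusted over the list alone. ADM was lower by -0.94 and NDRG1 by -0.62 (0.0121), the latter lost without restricted_9085 (0.0606) or restricted_9073 (0.0632). The anterior HOX list was higher by 0.59 (0.00436; adjusted p = 0.158 with an estimated correlation), with 7 of 13 higher and 2 lower, and 7 and 3 adjusted over the list alone. HOXA2 (2.25), HOXB5 (2.89) and HOXB6 (1.97) were higher and HOXC6 (-2.09, 2 of 3 probes) lower in 8 of 8 fetuses, and with the series matrix values this list was not called (0.115). The cell cycle list was lower by -0.26 (0.00982; adjusted p = 0.74 with an estimated correlation), with 6 of 24 passing and 6 adjusted over the list alone, MCM5 by -1.03 and MCM7 by -0.68. It was lower in 5 of 8 fetuses, and its call ended without restricted_9075 (0.101) or control_8009 (0.2). Oxidative phosphorylation genes were called with the block (0.11; 0.0503 without it and 0.0286 with it; adjusted p = 0.635 with an estimated correlation).

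PPARG was higher in omental than femoral cells by 1.95 ± 0.23 (5.23e-05) and CD36 by 2.01 ± 0.42 (0.0049, at least 3.33-fold, 7 of 8 fetuses), while CEBPA was lower by -1.64 ± 0.22 (0.000155). With the series matrix values CD36 (0.42) and CEBPA (0.114) did not pass. IGF1 was higher by 0.74 and the binding protein IGFBP3 lower by -0.65 (0.00955; 0.0505 without restricted_9073). Among imprinted genes, CDKN1C (1.88) and MEG3 (0.58) were higher and DIRAS3 (-2.14) lower in 8 of 8 fetuses (2.02e-05 to 0.000277). Cartilage protein COMP was lower by -2.46 and bone protein SPP1 higher by 2.06. The keratin genes parted, with KRT19 higher by 1.75 and KRT7 lower by -1.15. The glucocorticoid receptor gene NR3C1 (-0.82) and the metallothionein MT2A (-2.32) were lower, as were HOXC9 (-0.99, at least 1.44-fold), HOXC10 (-0.46, at least 1.14-fold) and TIMP3 (-1.66), and COL4A1 was higher (0.91). Adjusted p values of these 10 genes from COMP on ran from 5.42e-08 to 0.00715, and with the series matrix values COMP (0.0722) and KRT19 (0.0638) did not pass.

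**Figure D3:**
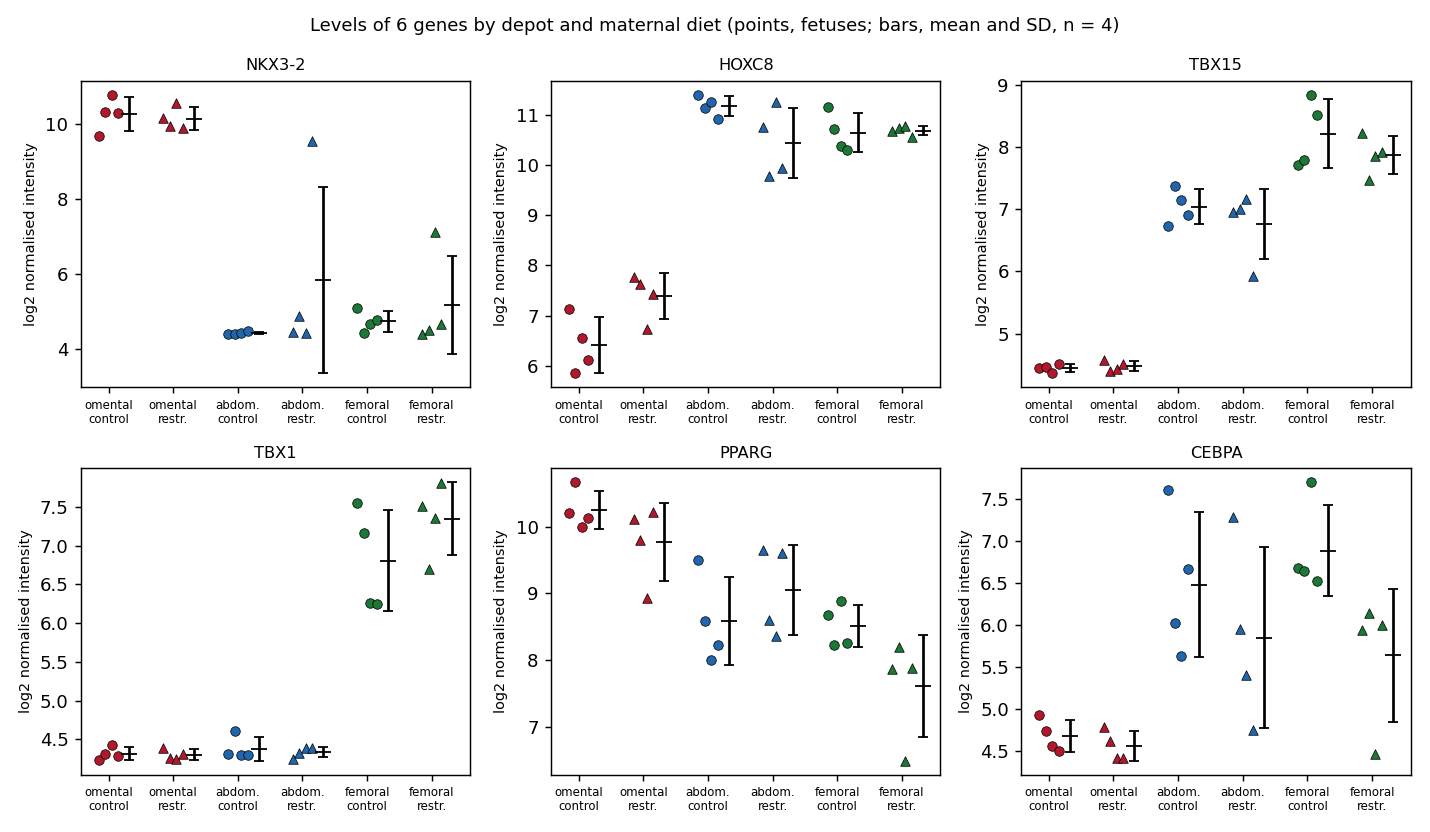
Log2 normalised intensity of NKX3-2, HOXC8, TBX15, TBX1, PPARG and CEBPA per fetus in 6 groups of depot and maternal diet, with bars for mean and SD (n = 4). NKX3-2 was high in all omental arrays, in the abdominal array of fetus restricted_9073 (9.55) and in part in the femoral array of fetus restricted_9075 (7.13), and TBX1 was high in femoral arrays alone.

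Abdominal and femoral cells, both subcutaneous, differed in few genes. TBX1 and LHX2 were higher in femoral cells, as were the cartilage gene COMP and the growth factor NRG1, while MEIS1, a partner of HOX proteins, was higher in abdominal cells. The anterior HOX list was called as higher in abdominal cells and the pericyte list as lower, with no single member passing. The thermogenic list was called as lower, with 2 of 5 genes positive and 3 negative and TBX1 alone passing. Of 16933 probes 665 had an unadjusted p under 0.05, against 847 by chance. Limma called 12, 4 higher and 8 lower in abdominal cells, which were 1 gene higher and 6 lower. The series matrix values gave 3 higher and 3 lower. With the fetus as a block 30 were called. Without control_9017 or control_8011 the count was 8.

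TBX1 was lower in abdominal cells by -2.72 ± 0.19, at 4.36 ± 0.11 against 7.08 ± 0.60 (SD, n = 8 and 8; adjusted p 5.3e-06, at least 4.94-fold), with 2 of 3 probes in this direction. LHX2 was lower by -1.65 ± 0.13 (1.19e-05, at least 2.37-fold) and C1orf53 by -0.98 ± 0.11 (0.00063), all in 8 of 8 fetuses, and these calls were kept with any fetus left out. MEIS1 was higher by 0.90 ± 0.13 in 8 of 8 (0.00932) and did not pass without control_9017 (0.0599), control_9087 (0.0856) or control_8011 (0.0892). COMP was lower by -1.51 ± 0.25 (0.0359; 0.131 without control_9017, 0.192 without restricted_9085, 0.215 without control_9087, 0.219 without control_8011 and 0.178 without restricted_9073). NRG1 was lower by -1.10 ± 0.17 (0.0137; 0.0634 without control_9017, 0.139 without control_8011, 0.0584 without control_8009 and 0.108 without restricted_9073). TMEM59L was lower by -0.55 ± 0.09 (0.0335) and kept its call only without restricted_9075 (otherwise 0.0885 to 0.192). With the series matrix values COMP (0.298), NRG1 and TMEM59L (each 0.141) did not pass. TBX15 (-1.14 ± 0.20, 0.0578) passed with the block (0.0457), with array weights (0.0359) and with all 24 arrays in 1 fit (0.000512 with a random block and 0.00256 without). PRRX1 (-0.56 ± 0.14, 0.401) passed with the block (0.0305) or a random block (0.0396).

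The anterior HOX list was higher in abdominal cells by 0.36 (1.98e-07), with 0 of 13 passing over all probes and 5 adjusted over the list alone, among them HOXA2 (0.92, 0.228) and HOXB6 (0.77, 0.304). With all 24 arrays and the fetus as a random block, which uses the pairing of depots, HOXA2 (0.0087), HOXB6 (0.0217) and PDGFRB (0.0291) passed. Pericyte markers were lower by -0.44 (0.000249), with 0 of 8 passing and 1 adjusted over the list alone, PDGFRB (-0.50, 0.592), and ANPEP differed by -0.62. The thermogenic list was lower by -0.68 (0.000249), with TBX1 as its 1 passing gene in either count, and was not called with the series matrix values (0.96) or without background correction (0.958). These 3 lists held with an estimated correlation, each at 0.0112. Cell cycle genes were higher by 0.21 with 24 of 24 positive, TK1 by 0.44 (0.000214; adjusted p = 0.705 with an estimated correlation). This list was higher in 4 of 8 fetuses and lower in 4, and without restricted_9085 its mean was 0.0643 (0.385). The subcutaneous identity list was lower by -0.22 (0.0104; adjusted p = 0.253 with an estimated correlation; 0.0521 without control_8009 and 0.128 without restricted_9073), with 0 of 10 passing and 2 adjusted over the list alone. The preadipocyte list was lower by -0.23 (0.0194; adjusted p = 0.0754 with an estimated correlation; 0.0728 without restricted_9075, 0.375 without a filter and 0.241 with probes detected on every array), with 0 of 16 passing and 3 adjusted over the list alone, among them JAG1 (-0.62) and CD34 (-1.62). Skeletal muscle markers were higher by 0.30, DES by 0.40 (0.0194; adjusted p = 0.465 with an estimated correlation; 0.0997 without restricted_2820), but without control_8009 their mean was 0.0282 (0.857). Cytokines were higher by 0.27, TNFAIP6 by 0.69 (0.0369; adjusted p = 0.805 with an estimated correlation), and the call ended without control_9017 (0.0824), restricted_9085 (0.0705), control_9087 (0.108), restricted_2820 (0.0959) or control_8009 (0.0806). With the abdominal array of restricted_9073 left out, 5 lists were called in place of 8. With the block, interferon response (-0.18; 0.132 and 0.00629), hypoxia (0.08; 0.335 and 0.0187) and epithelial markers (-0.31; 0.116 and 0.0398) were called too. None held (adjusted p = 0.834, 0.921 and 0.511 with an estimated correlation), and they had these signs in 5, 4 and 6 of 8 fetuses. The interferon mean was -0.0887 without restricted_2820.

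**Figure D4:**
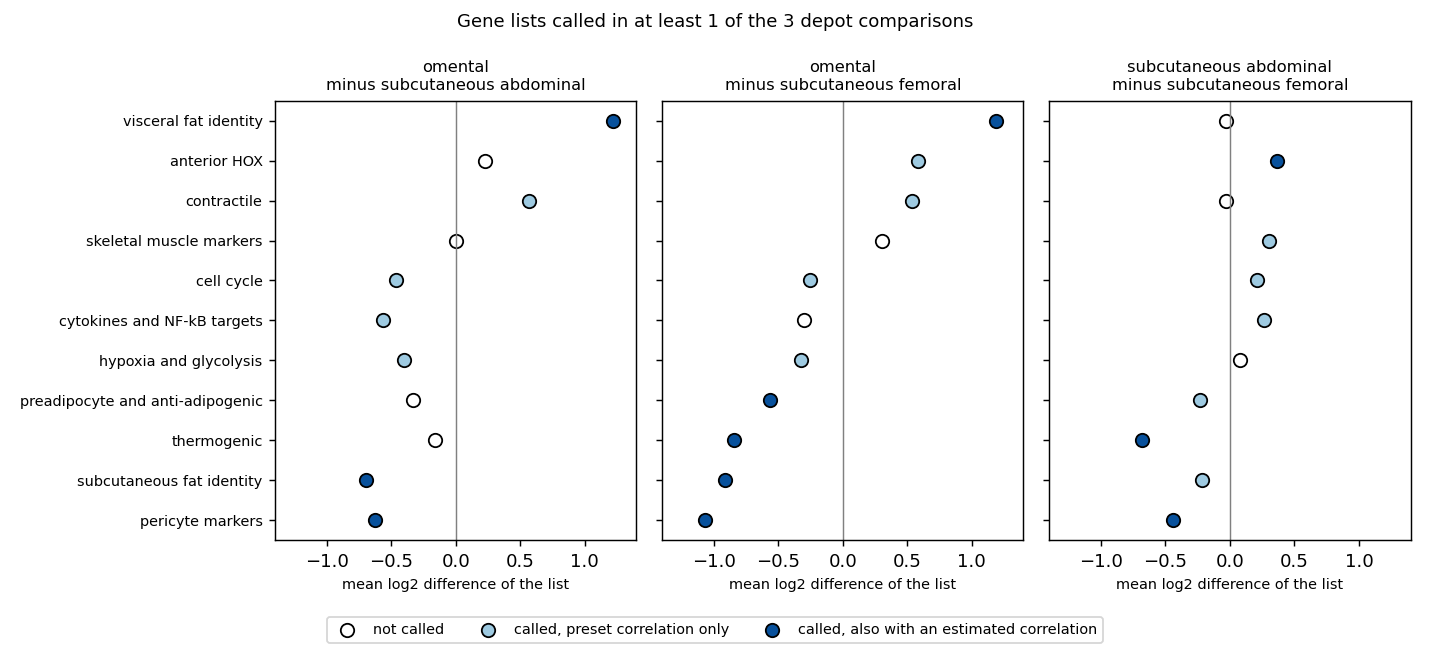
Mean log2 difference of each of 11 gene lists in the 3 depot comparisons, with dark points for lists called with a preset and an estimated correlation, pale points for the preset correlation alone and open points for lists not called. Visceral identity was higher and subcutaneous identity lower in omental cells against either subcutaneous depot, at means of 1.22 and -0.70 against abdominal and 1.19 and -0.92 against femoral cells.

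Of the 29 lists, 12 were called in no comparison without the fetus as a block, though glucocorticoid targets and cholesterol synthesis were called in interactions with it. Their lowest unblocked adjusted p over the 10 comparisons was 0.0515 for posterior HOX, 0.0553 for glucocorticoid targets, 0.0702 for unfolded protein and amino acid stress, 0.0817 for the insulin-like growth factor axis, 0.0821 for cholesterol synthesis and 0.0835 for mesothelial markers. It was 0.162 for Schwann and neural markers, 0.219 for macrophage and blood markers, 0.242 for endothelial markers, 0.54 for hindlimb identity, and 0.576 for adipocyte differentiation and for bone and cartilage.

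Within control fetuses, omental and abdominal cells differed in 388 probes (limma; 217 higher, 171 lower; 778 with the fetus as a block). Within restricted fetuses they differed in 0, with 1206 at an unadjusted p under 0.05 against 2224 in controls. Leaving out control_9087, control_8011 or control_8009 gave 184, 216 and 151 in controls, and leaving out restricted_9073 gave 31 in restricted fetuses. Omental and femoral cells differed in 1203 probes in controls (680 without control_8011, 579 without control_8009) and 190 in restricted fetuses (711 with the block; 48 without restricted_9085, 310 without restricted_2820, 80 without restricted_9075, 10 without restricted_9073). Abdominal and femoral cells differed in 9 probes in controls (3 without control_9017, 1 without control_9087, 0 without control_8011, 4 without control_8009) and 3 in restricted fetuses (1 with the block; 1 without restricted_2820 and 0 without restricted_9085, restricted_9075 or restricted_9073). Whether depots differed less in restricted fetuses rests on the interactions, which called no probe.

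Diet by depot interactions asked whether diet acted differently in different depots. Visceral identity genes were the clearest: the diet difference was lower in omental than in abdominal cells, where restricted fetuses had the higher values. Oxidative phosphorylation genes had their higher diet difference in femoral cells, against either other depot, though neither call held (adjusted p = 0.435 and 0.757 with an estimated correlation). Limma called 0 probes in each of the 3 interactions, with 330, 392 and 322 at an unadjusted p under 0.05, and 0 with the block, with 583, 688 and 722.

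The visceral list interaction of omental and abdominal cells was -0.62 with 9 of 10 genes negative (2.43e-05), and held with an estimated correlation (0.0323) but not without a filter on dim probes (0.204). Over all probes 0 of its genes passed and 1 did adjusted over the list alone, HAND2 (-0.71 ± 0.18, adjusted p over all probes 1), while TCF21 differed by -1.74 ± 0.73 without passing. Without fetus restricted_2820 and the abdominal array of restricted_9073, it was -0.176 and not called (0.117). Leaving out control_9017, restricted_9085, restricted_9075, restricted_9073 or the abdominal array of restricted_9073 gave 2, 3, 3, 4 and 3 called lists in place of 1. HOXC8 (1.72 ± 0.46) and ARPP21 (0.93 ± 0.17) did not pass. Interferon genes were called with the block (0.52; 0.224 without it and 0.00451 with it; adjusted p = 0.879 with an estimated correlation). Fetus restricted_2820 carried most of this, since without it the diet means were 0.203 in omental and 0.0561 in abdominal cells.

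For omental and femoral cells, the oxidative phosphorylation interaction was -0.18 with 24 of 24 genes negative, COX7B by -0.46 and NDUFB5 by -0.32 (5.17e-05; adjusted p = 0.435 with an estimated correlation). Pericyte markers differed by 0.37 (0.0329; adjusted p = 0.25 with an estimated correlation), with CD248 (1.38 ± 0.39) the 1 gene adjusted over the list alone and ANPEP at 0.52, and the call ended without control_9017 (0.0571), restricted_2820 (0.0679) or control_8009 (0.219), and without a filter (0.193). Extracellular matrix genes differed by 0.13, LOXL1 by 0.62 and COL15A1 by 0.61 (0.0329; adjusted p = 0.332 with an estimated correlation), and the call ended without control_9017 (0.0571), restricted_9085 (0.147), control_9087 (0.126) or control_8009 (0.248), and with median scaling, where the list differed by 0.0363 (0.0917). Leaving out control_9017 or control_8009 gave 1 list, and restricted_9085 or control_8011 gave 5, in place of 3. With the block, cholesterol synthesis (-0.16; 0.0821 and 0.00668) and interferon response (0.36; 0.32 and 0.000561) were called too. Neither held (adjusted p = 0.646 and 0.839 with an estimated correlation), and without restricted_2820 the interferon diet means were 0.203 in omental and 0.0179 in femoral cells. For abdominal and femoral cells, the oxidative phosphorylation interaction was -0.18, SDHD by -0.40 and COX5B by -0.30 (0.000132; adjusted p = 0.757 with an estimated correlation). The visceral one was 0.41, FOXF1 by 0.81 and GPC4 by 0.66 (0.00998; adjusted p = 0.467 with an estimated correlation), lost without restricted_2820 (0.0637), control_8009 (0.17), restricted_9073 (0.23) or the abdominal array of restricted_9073 (0.237), without a filter (0.238), with probes detected on every array (0.249) and with the series matrix values (0.119). Without control_8009, 1 list was called in place of 2. With the block, glucocorticoid targets (0.43; 0.0553 and 0.0211) and cholesterol synthesis (-0.14; 0.367 and 0.0379) were called too, and neither held (adjusted p = 0.757 and 0.938 with an estimated correlation).

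Diet differences across the 16933 probes correlated between depots with a Pearson r of 0.534 for omental and abdominal, 0.538 for omental and femoral, and 0.566 for abdominal and femoral cells. These are correlations across genes, which are not independent replicates. The other splits of the 8 fetuses had medians of 0.429, 0.468 and 0.522, since depots of a fetus vary together, and the exact one-sided permutation p was 0.0571, 0.171 and 0.286 over 35 splits. The fetus within its diet held a median of 34.6% of a probe's variance, depot 9.12%, diet 3.41% and the rest 41.2%. These shares are not adjusted for the number of levels of a factor. By chance the 8 fetuses take a larger share than depots or diets, so the shares cannot be ranked against each other. Other splits of the fetuses gave diet a median of 3.04% (exact one-sided permutation p 0.2).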

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

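Tests of maternal diet for fetuses restricted_2820 and restricted_9073 were chosen after the result was seen. So were tests of exchanged samples in the latter and of the other ZNF331 probe. An array stood apart from the other 3 of its group when the gap to its nearest neighbour, divided by the range of the 4 arrays, was above Dixon's critical value for a group of 4. Chance alone sets about 1 in 20 groups apart, so single cases carry little weight. The ratio does not measure the size of a gap, so small gaps near background can stand apart too. Among the genes named, 51 of 690 groups had such an array, against 34.5 by chance. Among the lists named it was 8 of 102, against 5.1, and among array measures 2 of 24, against 1.2. Fetuses restricted_2820 and restricted_9073 stood apart most often.

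Fetus restricted_2820, whose mother was restricted, had high interferon response genes in all 3 depots. The list's mean stood apart in abdominal cells (ratio 0.874) and femoral cells (0.833), and over its 3 depots the fetus averaged 7.58 against 5.30 ± 0.10 (SD) in the other 7. IFI44 stood apart in omental cells (0.894, at 9.52 against 4.71) and femoral cells (0.941). The second principal component (0.854), the hypoxia and glycolysis list (0.947), the cytokine CXCL8 (0.876) and SOD2 (0.870) stood apart in its omental cells. The thermogenic list was slightly lower in omental cells (0.839, at 5.215 against 5.266) and higher in abdominal cells (0.924, at 5.757 against 5.326). EBF2 was high (0.876) and NDUFB5 low (0.866) in abdominal cells, and GPC4 was low (0.857) in femoral cells. CD36 stood apart in femoral cells too (0.940, at 4.70 against 4.46), though it was detected on no femoral array.

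For the interferon genes of fetus restricted_2820, an excess of 2.27, the tables argue against 2 explanations. Array signal predicted an excess of 0.122 ± 0.102 by the line of the other 7 fetuses. Maternal diet, without this fetus, gave a difference of 0.0924 between the other 3 restricted fetuses and the 4 controls (exact permutation p 0.257). Immune cells among the cultured cells stay open. Macrophage and blood markers had a median excess of -0.0112 ± 0.145 against 2.63 for the interferon genes, below the bound set beforehand for immune cells. But 9 of the 16 markers were detected on no array and so lay at background, so that median decides little. Of the detected markers, CD14 had an excess of 2.30 and was also detected on 21 arrays of the other fetuses. The others had little or none: CD68 (-0.04), ITGB2 (0.20), CD74 (-0.07), LYZ (0.002), HLA-DRA (-0.005) and LAPTM5 (0.02). An infection of the cultures or of the fetus, or a response of its own, may explain it and was not tested.

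The abdominal cells of fetus restricted_9073 lay between omental and other abdominal cells. ISL1 (0.985), ALDH1A1 (0.938), PDLIM3 (0.933), CD36 (0.923), NKX3-2 (0.910, at 9.55 against 4.59), SNAP25 (0.904) and ALDH1A2 (0.891) were high, and CD248 (0.905) and TBX15 (0.832) were low. ITGA8 was low in its femoral cells (0.835).

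These cells had shares of omental level of 0.614 from 30 genes high in omental cells and 0.821 from 43 low there. A mixture would give equal shares, and they differed by 0.207, above the bound of 0.15 set beforehand. That bound was wrong: the other 7 abdominal arrays, taken as unmixed, had differences of 0.0129 to 0.628. A mixture or cells of mixed character may explain the pattern. An exchange with the omental sample is argued against, as that array had a share of 1.03. Maternal diet acting on every restricted fetus is argued against, as the other 7 abdominal shares from high genes were -0.0635 to 0.0530. The mean share gave -0.191 for the other 3 restricted fetuses minus the 4 controls (exact permutation p 0.0286, the smallest 35 splits allow). This came mostly from low genes.

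ZNF331 was lower in restricted fetuses on 1 probe (-0.84 averaged over depots), and in abdominal cells fetus restricted_9075 stood apart with a higher value (0.866, at 4.56 against 4.37). A fall of every ZNF331 transcript would lower the other tested probe too, which differed by 0.0133 ± 0.0491. As that probe was detected on only 3 control and 4 restricted arrays, the test decides nothing. A transcript form or a sequence difference under the probe, carried by control or by restricted fetuses, may explain the value and was not tested.

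Several cases lay in fetus restricted_9075. The imprinted list was high in its abdominal cells (0.925). In its femoral cells NKX3-2 (0.904, at 7.13), ALDH1A2 (0.914) and TIMP3 (0.885) were high, and ABLIM1 (0.918) and CEBPA (0.879) were low. In its omental cells CALB2 (0.850) and RCAN1 (0.910) were high. In fetus restricted_9085, IGF2 (0.915) and MME (0.951) were high and SPINT2 (0.924), TCF7L2 (0.891) and TK1 (0.888) low in omental cells, KITLG (0.844) was high in abdominal cells and LOXL1 (0.899) low in femoral cells. No explanation was tested for these or for those that follow.

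Among control fetuses, control_8009 had a high mean signal in femoral cells (0.865) and high skeletal muscle markers in omental (0.837) and abdominal cells (0.850), with low TOP2A in omental (0.840) and low TMEM59L in abdominal cells (0.876). Fetus control_9087 had high CXCL8 (0.924), FOXF1 (0.893) and PITX1 (0.890) and low DIRAS3 (0.851) in omental cells. It had high IFI44 (0.843) and PDLIM3 (0.8291) in abdominal cells, and high TMEM59L (0.880) and low SPINT2 (0.909) in femoral cells. TBX1 stood apart in its abdominal cells (0.944, at 4.60 against 4.30), though the called probe was detected on no abdominal array. Fetus control_9017 had high NDUFV2 (0.917) and SDHD (0.841) in omental cells, low UQCRH (0.887) in abdominal cells, and high KRT7 (0.910) and low LDHA (0.831) in femoral cells. Fetus control_8011 had high EPCAM (0.859) in omental and high CEBPA (0.867) in femoral cells.

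Interactions of diet and depot were called for 4 lists in 6 tests, though other splits of the fetuses called as many lists too often to exclude chance. These were the visceral identity list between omental and abdominal cells (-0.62) and between abdominal and femoral cells (0.41), oxidative phosphorylation between omental and femoral cells (-0.18) and between abdominal and femoral cells (-0.18), and extracellular matrix (0.13) and pericyte markers (0.37) between omental and femoral cells. Only the first held with an estimated correlation. It was lost without a filter (0.204) or without restricted_2820 and the abdominal array of restricted_9073 (-0.176, 0.117).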

How the results depend on the processing

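The cause of each change below was not tested, except that settings with fewer arrays or probes tested less and the list test with an estimated correlation widened its error. Leaving out the abdominal array of fetus restricted_9073, alone, with fetus restricted_2820 or with the block, and leaving out fetuses within a diet, were chosen after seeing the data, as was the block within a diet. A slide block was not run, because the column names give no slides. Of values for named genes under alternatives, 3771 kept their direction and side of the threshold, 154 lost and 22 gained a call, and 0 reversed. Of values for lists, 927 kept theirs, 189 lost the call and 2 reversed: the cell cycle list, maternal diet in omental cells, without control_8009 (-0.0051, in a range up to 0.443 over the fetuses left out) and the interferon response list, maternal diet in subcutaneous abdominal cells, without restricted_2820 and the abdominal array of restricted_9073 (0.0203, against the list's direction in the test). With the series matrix values, femoral diet gave 1 probe and 2 lists, omental versus abdominal cells 353 probes, abdominal versus femoral cells 6, and the interaction of these last 1 list. Agreement of diet effects fell to 0.263 (omental and abdominal), 0.273 (omental and femoral) and 0.263 (abdominal and femoral). Without background correction these counts of calls were the same, except 7 for abdominal versus femoral cells. The omental and abdominal interaction gave 2 lists. Median scaling gave 6 lists for abdominal diet and 0 probes for averaged diet. Without a filter on dim probes, omental diet gave 3 lists, omental versus abdominal cells 347 probes and 11 lists, and the interactions 0, 1 and 1 lists in the order omental and abdominal, omental and femoral, abdominal and femoral. The variance shares were then 7.25% for depot, 2.52% for diet, 28.7% for fetus within diet and 54.8% for the rest. With probes detected on every array compared, omental diet gave 1 list, averaged diet 0 probes and 2 lists, the depot comparisons 431, 1102 and 2 probes, and the abdominal and femoral interaction 1 list. Sex as a covariate gave 2 lists for femoral diet and 0 probes for averaged diet. Female fetuses alone gave 3 probes for each of omental, abdominal and femoral diet, 0 for averaged diet, 5 lists for abdominal diet, 203 and 1035 probes for omental versus abdominal and omental versus femoral cells, and 3 and 4 lists for the omental and abdominal and the abdominal and femoral interactions. With 1 probe per gene, abdominal versus femoral cells gave 7. All probes of listed genes gave 6 lists for abdominal diet and 6 for the omental and femoral interaction. The fetus as a fixed replicate block gave 1439 probes for omental versus abdominal cells and 30 for abdominal versus femoral cells, 2, 5 and 4 lists for the interactions, 778 for omental versus abdominal cells in controls, and 711 for omental versus femoral and 1 for abdominal versus femoral cells in restricted fetuses. Besides the calls given with it in the results, the block changed no other call of a list or named gene. With the block and without the abdominal array of restricted_9073 these were 1432 and 28 probes, and 4 lists for the omental and abdominal interaction. All 24 arrays in 1 fit gave, with the fetus as a random replicate block (correlation 0.254), 4 probes for femoral diet, 22 for averaged diet, 1726 for omental versus abdominal cells, 44 for abdominal versus femoral cells and 1 list for the omental and femoral interaction. Without that block they gave 2 probes for omental diet, 3 probes and 2 lists for femoral diet, 19 for abdominal versus femoral cells and 1 list for the omental and femoral interaction. This fit takes arrays of a fetus as independent, although they vary together. With an estimated correlation, lists called were 0 for each of the 4 diet comparisons (omental, abdominal, femoral and averaged), 3, 5 and 3 for the depot comparisons, and 0 for the omental and femoral and the abdominal and femoral interactions. Without restricted_2820 and the abdominal array of restricted_9073, abdominal diet gave 1 probe and 1 list, averaged diet 2 probes and 1 list, omental versus abdominal cells 1037 probes, the omental and abdominal interaction 1 probe and 0 lists, and the abdominal and femoral interaction 4 lists. Leaving out each fetus in turn gave 0 to 2 probes and 1 to 5 lists for omental diet, 0 to 1 and 1 to 7 for abdominal diet, 0 to 5 and 2 to 6 for femoral diet, and 0 to 3 and 0 to 6 for averaged diet. It gave 276 to 1082 probes and 6 to 9 lists for omental versus abdominal cells (the abdominal array of restricted_9073 alone included), 1196 to 1956 and 8 to 11 for omental versus femoral cells, and 8 to 14 and 5 to 8 for abdominal versus femoral cells. The interactions gave 0 to 0 probes and 1 to 4, 1 to 5 and 1 to 3 lists. Within controls the depot comparisons gave 151 to 275, 579 to 986 and 0 to 4 probes, and within restricted fetuses 0 to 31, 10 to 310 and 0 to 1. Agreement of diet effects ran from 0.476 to 0.548, 0.487 to 0.560 and 0.478 to 0.632, and the variance shares from 9.61% to 11.4% for depot, 3.60% to 4.49% for diet, 30.3% to 34.2% for fetus within diet and 39.7% to 41.8% for the rest. The list means of anterior HOX (omental versus femoral cells, -0.12) and of skeletal muscle markers (abdominal versus femoral cells, -0.35) with the series matrix values differ in sign from their test. Array weights and an intensity trend with robust moderation moved no count of calls past 1.5 times. The filter and the background correction act on dim probes.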

Other observations

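All tests of other splits of the samples were planned before the results were seen. The exchanges of depots within fetuses are extra counts of the same kind.

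Omental progenitors combined a high level of PPARG with a low level of CEBPA against both subcutaneous depots. These factors usually rise together as a progenitor turns into a fat cell, yet the adipocyte differentiation list was called in no comparison (lowest adjusted p 0.576). Femoral cells carried LHX2 and TBX1. In abdominal cells of the same fetuses LHX2 was not detected on any array, nor was the called probe of TBX1, though another TBX1 probe was detected on some, so a pair of subcutaneous depots differed in a pair of patterning genes after culture, freezing and regrowth. Retinoic acid enzymes parted the same way as NKX3-2, with ALDH1A1 and ALDH1A2 higher in omental than abdominal cells and high in the abdominal cells of fetus restricted_9073.

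Chance could be excluded for probe counts of the depot comparisons at the threshold used. Of 100 splits of the 16 arrays into 8 and 8 with both diets balanced, 1 gave as many calls as omental versus abdominal cells (the real split; 680, highest other 555), 1 as many as omental versus femoral cells (1780, highest other 1004) and 4 as many as abdominal versus femoral cells (12, highest other 260). For this last pair 64 of 100 splits gave as many probes at an unadjusted p under 0.05 (665, highest other 2665). A split with 260 calls, many times the real count, points to a structure of the samples, as arrays of a fetus vary together. The real split parts every pair of arrays of a fetus, and when depots were exchanged within fetuses, so that as many pairs were parted, 1 of 100 exchanges gave as many calls in each comparison (the real one; highest others 294, 583 and 0). For lists, 13 of 100 splits gave as many as omental versus abdominal cells (7, highest other 12) and 8 as many as abdominal versus femoral cells (8, highest other 11), so chance could not be excluded. For omental versus femoral cells 3 of 100 did (9, highest other 13). Exchanges of depots within fetuses gave as many lists in 15, 6 and 2 of 100 (highest others 9, 11 and 9, in the order omental versus abdominal, omental versus femoral, abdominal versus femoral cells). The 2 kinds of split thus disagree for the last 2 comparisons, and whether chance explains their list counts is not settled.

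Within controls, 1 of 35 splits gave as many calls for omental versus abdominal cells (388, highest other 13) and 1 for omental versus femoral cells (1203, highest other 10). Within restricted fetuses 1 did for omental versus femoral cells (190, highest other 39), but 3 of 35 gave as many probes at an unadjusted p under 0.05 (1684, highest other 2177), and the calls dropped to 10 without restricted_9073, so the measures disagree. Many of the other splits in these 3 comparisons keep both arrays of a fetus on 1 side, unlike the real split. Exchanges of depots within fetuses, which part every pair as the real split does, are among the other splits. They therefore gave at most 13, 10 and 39 calls. But 4 fetuses allow too few such exchanges to exclude chance, so none of the 3 comparisons excludes it. For omental versus abdominal cells within restricted fetuses the count was 0, which all 35 splits must match (highest other 47), so it tests nothing. At an unadjusted p under 0.05, 6 of 35 splits gave as many (1206, highest other 2164). Abdominal versus femoral cells were matched by 4 of 35 splits in controls (9, highest other 41) and 4 of 35 in restricted fetuses (3, highest other 172), so chance could not be excluded, and the last of these points again to a structure of the samples.

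For maternal diet, chance could not be excluded in any depot. The counts of calls test nothing within depots, since all 35 splits of the 8 fetuses must match a count of 0 in omental diet (0, highest other 4), abdominal diet (0, highest other 1) and femoral diet (0, highest other 1). Counts at an unadjusted p under 0.05 were matched by 17 of 35 splits for omental diet (804, highest other 1444), 11 for abdominal diet (824, highest other 1671), 5 for femoral diet (1050, highest other 1174) and 6 for averaged diet (1051, highest other 1441). For averaged diet 9 of 35 gave as many calls (1, highest other 3). For lists, 5 of 35 splits gave as many for omental diet (6, highest other 8), 25 for abdominal diet (3, highest other 10), 18 for femoral diet (4, highest other 7) and 20 for averaged diet (4, highest other 9). For the interactions all 35 splits must likewise match counts of 0, in omental and abdominal (0, highest other 1), omental and femoral (0, highest other 0) and abdominal and femoral cells (0, highest other 0). At an unadjusted p under 0.05, 26, 21 and 16 of 35 splits gave as many probes in that order (330, 392 and 322, highest others 669, 840 and 538), so chance could not be excluded. Of lists, 32 of 35 gave as many for omental and abdominal (1, highest other 7), 4 for omental and femoral (3, highest other 4) and 26 for abdominal and femoral cells (2, highest other 5).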
